A study of Mus musculus with 8 samples.

How the data were processed

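Polyadenylated RNA of splenic mononuclear cells from leukaemic mice was extracted with a mirVana kit and sequenced on a NovaSeq 6000, per the labels' protocols. The values analysed were FPKM in 1 table of 54018 gene identifiers and 8 columns, as the authors deposited them. The submitters' processing notes name CASAVA and Cufflinks without versions, and the aligner, genome build, annotation and use of strand are not given in the sources used here. FPKM divides fragments by transcript length and library total, so values of a library move with its most abundant transcripts, and the table holds no counts. Identifiers were matched to the GENCODE M21 annotation of GRCm38, which named 53865 of them, and coordinates printed are from that annotation. Of its identifiers 1585 were not analysed here. Separately, 8 of 760 list gene symbols had no match among the identifiers analysed. Of all identifiers 25157 were at 0 in every library.

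An exact 0 can be a failed estimate in such a table. For 28 genes a library was listed at 0 although the median was above 10 FPKM. Trip12, for example, was at 0 in knockdown replicates 1, 2 and 5 and had 80.9 FPKM in knockdown replicate 4, and Kmt2d was at 0 in knockdown replicates 1 and 2. Depth was estimated from the steps between low FPKM values of transcripts of at least 1500 bases, which are whole multiples of the value of 1 fragment. Between 84.2% and 95.5% of those values lay within 5% of a whole multiple. FPKM summed to 572660 in control replicate 4 and to between 671732 and 762888 in the other 7 libraries.

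The labels gave the groups and replicate numbers. The comparison was knockdown (n = 4) against control (n = 4) on log2(FPKM + 1), with genes of at least 1 FPKM in at least 4 of 8 libraries. Genes were tested with limma 3.58.1 with a mean-variance trend in R 4.3.3, with Benjamini-Hochberg adjustment over 12890 genes and a threshold of 0.05. No covariate was used. The design, lists, rule for naming genes and most alternatives were fixed before the data were examined. The 40 lists with at least 5 expressed members were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Levels of marker lists with at least 3 expressed members, Kdm1a and Ighv shares were compared with two-sided exact permutation tests over 70 assignments, whose smallest p is 0.0286. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

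Genes were named by rule. Kdm1a came first, then, of genes past the threshold whose groups did not overlap, the 12 largest rises and up to 12 largest falls, leaving out immunoglobulin and T cell receptor segments, predicted models and sex markers. Only 8 falls met the rule. Then came 2 to 4 members with the smallest p of each list described, the choice of lists to describe being made after their results were seen, and fixed genes (Rcor1, Gfi1, Gfi1b, Kdm1b, Cd5, Bcl2, Myc, Mki67 and Tcl1). Some genes that the rule names are not reported here.

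The fit was tested on simulated data with the control means and the spread of these libraries, each gene drawn independently. Changes were planted only as rises and not in genes of low control level, so recovery of falls and of rises from low levels was not tested. Over 5 runs of 12890 genes it recovered 50.8% of genes changed 2-fold, 86.4% of those changed 4-fold, 94.4% at 8-fold and 97.2% at 16-fold, and called 42 of 63450 unchanged genes. A list shifted 2-fold was called in 5 of 5 runs and 0 of 200 unchanged lists were called. Since the simulated genes were independent, this does not show how often unchanged lists of correlated genes are called.

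Alternatives changed the pseudocount (0.1 or 5), the filter, the scaling, the test, the threshold, each library left out in turn, a block by replicate number and a covariate for B cell level. Those added after seeing the data were sex and erythroid level as covariates, both replicate 4 libraries left out, and failed estimates left out.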

Results

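RNA abundance was measured in 8 libraries of splenic mononuclear cells from leukaemic C57BL/6 mice carrying the Eµ-TCL1A transgene, a mouse model of chronic lymphocytic leukaemia in which the human TCL1A oncogene is expressed in B cells. In 4 libraries a doxycycline-inducible construct was present to lower the histone lysine demethylase Kdm1a (called knockdown here; replicates 1, 2, 5 and 4), and 4 libraries carried the leukaemia transgene alone (called control; replicates 1 to 4). The labels do not say whether the control mice received doxycycline. The comparison between the groups asks which transcripts differ in the leukaemic spleen when Kdm1a is lowered. The labels call the source leukaemic mice but do not tie each library to 1 animal, so p-values measure the spread between these libraries. Values were FPKM (fragments per kilobase of transcript, scaled to library size), and between 12567 and 13138 genes reached 1 FPKM per library. Depth estimated from the steps of low values lay between 37200000 and 43700000 fragments, so that 1 fragment on a transcript of 1 kilobase was worth 0.0229 to 0.0269 FPKM.

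Kdm1a (ENSMUSG00000036940, chromosome 4, 136550540 to 136602723, minus strand, GRCm38) had 20.2, 21.0, 15.6 and 15.5 FPKM in knockdown replicates 1, 2, 5 and 4. The control libraries had 24.2, 21.2, 24.1 and 31.1 FPKM in replicates 1 to 4. The knockdown mean of 18.1 ± 2.96 FPKM (SD, n = 4) was 71.9% of the control mean of 25.1 ± 4.19 FPKM (SD, n = 4), and the groups did not overlap. The log2 difference was −0.46 with a 95% interval of −0.86 to −0.05. A two-sided exact permutation test over the 70 assignments of the libraries gave p = 0.0286, the smallest it can give, while the adjusted p of limma over all genes was 0.223. The span of Kdm1a overlaps those of 2 annotated genes, and reads of overlapping genes may not be told apart where strand was not used.

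**Figure D1:**
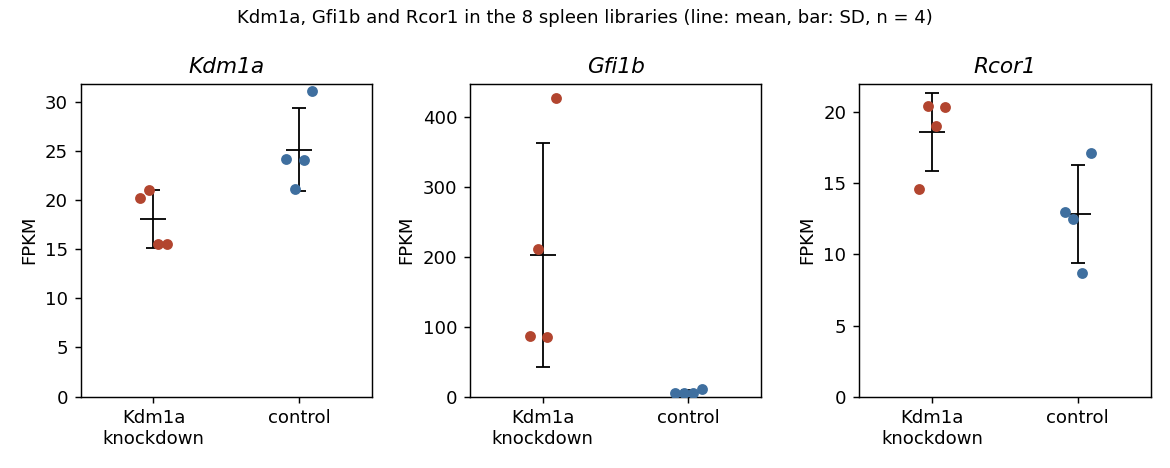
FPKM of Kdm1a, Gfi1b and Rcor1 (vertical axes, from 0) in the knockdown and control libraries. Each point is 1 library, the line is the mean and the bar the SD (n = 4). Kdm1a averaged 18.1 against 25.1 FPKM, Gfi1b 203 against 6.35 FPKM, and Rcor1 18.6 against 12.8 FPKM.

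The first principal component of the 12890 expressed genes carried 43.5% of the variance and the second 16.4%. All knockdown libraries had negative scores on the first component and all control libraries positive ones, from −78.3 in knockdown replicate 4 to 57.7 in control replicate 4. These 2 libraries stood apart. Knockdown replicate 4 had the highest erythroid marker level, 8.65 against 4.75 to 6.33 on the log2 scale in the other 7 libraries. Control replicate 4 had the lowest share of mitochondrial FPKM, 7.47% against 9.94% to 15.1% elsewhere. Xist, the transcript of the inactive X chromosome, had 94.9 to 175 FPKM in the 4 knockdown libraries and 110 FPKM in control replicate 1, but at most 0.128 FPKM in control replicates 2, 3 and 4. The Y-linked gene Ddx3y had 11.7 to 31.5 FPKM in those 3 controls and was listed at 0 in the other 5 libraries. Group and sex were therefore nearly the same split of the libraries, with 1 female control. A group difference with sex as a covariate is thus the knockdown mean minus control replicate 1 alone, so only its size is given.

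**Figure D2:**
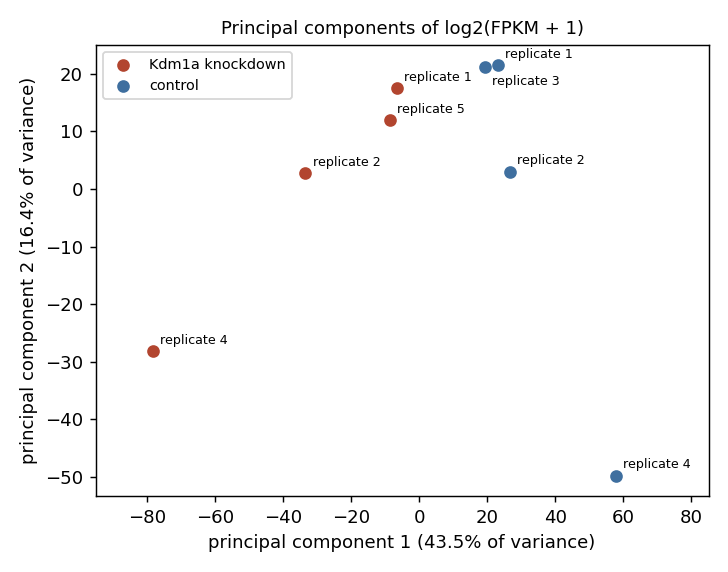
Scores of the 8 libraries on the first (43.5% of variance) and second (16.4%) principal component of log2(FPKM + 1), coloured by group and named by replicate. The knockdown libraries lie at negative values of the first component, and replicate 4 of each group lies farthest out.

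Lowered Kdm1a went with a predominance of higher transcripts. Of 12890 genes, 210 rose and 14 fell past an adjusted p of 0.05 (limma on log2(FPKM + 1)), and in each of these 224 genes the groups did not overlap. The median log2 change was 1.81 over the rises and −1.44 over the falls, and 127 of the 210 rises had a control mean under 2 FPKM. The 210 included 7 immunoglobulin or T cell receptor segment genes and 12 predicted gene models, the 14 falls 6 predicted models. Groups without overlap were found for 1689 genes, 13.1% of those tested against 2.86% by chance. At an unadjusted p under 0.05 there were 2480 genes, 2040 of them higher, where 644 would be due to chance. The median over all genes was itself 0.13 on the log2 scale, and 0.00 after median-of-ratios scaling or −0.03 after quantile normalization. The X chromosome held 4 of the 224 genes and 379 of all genes tested (Fisher's exact test p = 0.422).

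The count moved with most libraries left out. It was 8 without control replicate 4, 13 without knockdown replicate 2, 29, 46 and 90 without control replicates 3, 2 and 1, 317, 333 and 203 without knockdown replicates 1, 5 and 4, and 120 without replicate 4 of both groups. Over the settings that kept all libraries, sex as a covariate aside, it was between 2 and 761.

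The largest rise was that of Gfi1b, a zinc finger repressor of erythroid and megakaryocytic development that binds KDM1A (ENSMUSG00000026815, chromosome 2, 28609450 to 28621982). It had 87.4, 212, 85.4 and 427 FPKM in the knockdown libraries and 4.52, 4.64, 4.81 and 11.5 FPKM in the controls, a ratio of means of 31.9 and a log2 change of 4.56 ± 0.51 (SE; adjusted p = 0.00967). Gmpr, which encodes GMP reductase, followed with 31.8 ± 37.7 against 0.156 ± 0.062 FPKM (SD, n = 4) and a log2 change of 4.20. Podxl, the sialomucin podocalyxin of progenitor and endothelial surfaces, had 21.7 ± 15.9 against 0.092 ± 0.039 FPKM and a log2 change of 4.10. The other 9 of the 12 largest rises had log2 changes between 3.19 and 3.66. Among these were the metallothionein gene Mt2 (239 against 15.5 FPKM), the signalling adaptor Grb10 (18.1 against 0.410 FPKM) and Egfl7, a secreted factor and host gene of a microRNA (20.5 against 0.937 FPKM). Tfr2, a transferrin receptor of iron sensing, had 40.9 against 2.80 FPKM, and the transporter gene Slc45a3 24.3 against 1.69 FPKM with the smallest adjusted p of all genes (0.00514). Sdsl, Kcne3, Bex4 and Cda completed the 12, with knockdown means of 28.5, 15.4, 35.7 and 15.8 FPKM against 1.02, 0.211, 1.89 and 0.167 FPKM. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes under 1 FPKM. Mt2 is close in sequence to other metallothioneins, and Egfl7, Gmpr, Kcne3, Mt2 and Slc45a3 overlap other annotated genes, so their values are less certain.

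Genes of secondary neutrophil granules were among the falls. Ngp, which encodes neutrophilic granule protein, had 0.768 ± 0.585 against 24.9 ± 18.6 FPKM (SD, n = 4), a log2 change of −3.56 ± 0.56 (SE; adjusted p = 0.0189). Camp, the cathelicidin gene, had 0.372 ± 0.283 against 11.6 ± 9.23 FPKM and a log2 change of −2.97. Ltf, which encodes lactoferrin, had 0.492 ± 0.435 against 6.30 ± 4.27 FPKM and a log2 change of −2.11. The remaining 5 named falls were Platr17 (3.75 against 16.7 FPKM), the non-coding AI427809 (20.1 against 42.3 FPKM), the TNF family ligand gene Tnfsf18 (1.92 against 5.99 FPKM), Lman2l, which encodes a lectin of the secretory pathway (8.27 against 15.2 FPKM), and mmu-mir-3535. The last was listed at 0 in the 4 knockdown libraries and had 1.58, 1.86, 4.23 and 8.27 FPKM in the controls, a log2 change of −2.12 that depends on the added 1. It lies within Ncl on the same strand, so its value is uncertain. All 20 named genes kept their sign when any library was left out, which groups without overlap ensure. The number past the threshold ranged from 4 without control replicate 4 (Gfi1b, Grb10, Egfl7 and Slc45a3) to 18. It was 6, 8, 13 and 14 without knockdown replicate 2 and control replicates 3, 2 and 1.

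**Figure D3:**
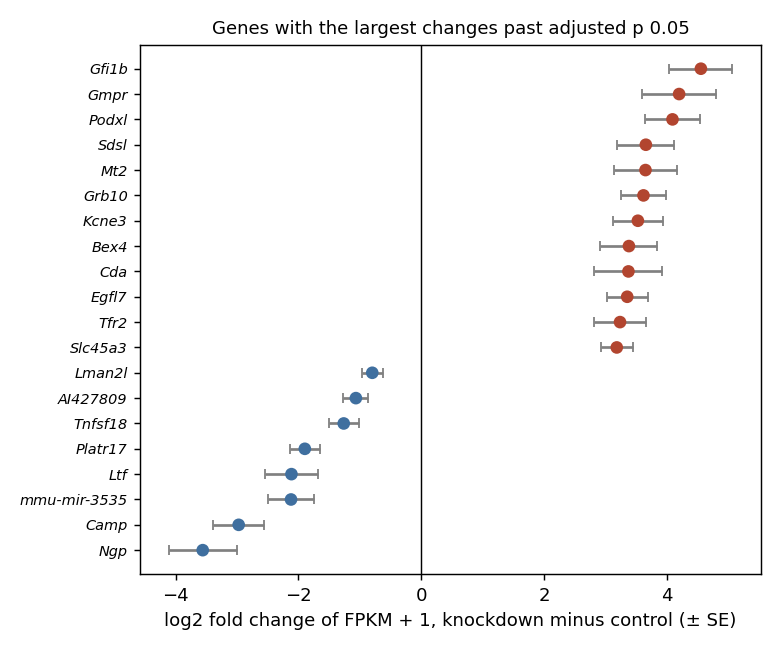
Log2 fold change of FPKM + 1 (horizontal axis, knockdown minus control, bars ± SE) of the 12 largest rises and the 8 named falls past adjusted p 0.05. Gfi1b stands at 4.56 and Ngp at −3.56.

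Some genes of early blood lineages were higher in the knockdown libraries. In the stem and progenitor list 3 of the 4 members that reached the expression filter rose, adjusted over the list alone, and 2 over all genes. These were Sox4, a transcription factor of progenitors (6.64 against 0.531 FPKM, log2 change 2.25), Kit, the stem cell factor receptor (15.4 against 4.03 FPKM, log2 change 1.69) and Gata2 (7.90 against 1.26 FPKM, log2 change 1.85). Myb, the other member, had 52.5 against 52.0 FPKM. In the erythroid list 5 of 19 members rose, adjusted over the list alone, and 1 over all genes, Gata1, the master regulator of red cell and megakaryocyte development (58.2 against 6.14 FPKM, log2 change 2.71). Epor, the erythropoietin receptor gene, had a log2 change of 2.02, Klf1, a red cell transcription factor gene, one of 2.05, and the carbonic anhydrase gene Car1 one of 1.95. The list did not move as a whole (mean log2 change 0.49, median 0.79; camera adjusted p = 0.335). Adjusted over the list alone, 1 member rose without knockdown replicate 2 and 3 without control replicate 2, while 5 rose and 4 fell without knockdown replicate 4. The highest erythroid level was that of knockdown replicate 4, and the mean of the erythroid list was −0.33 without it (adjusted p = 0.178) and −0.29 without replicate 4 of both groups (adjusted p = 0.548). With the B cell list level as a covariate the erythroid list was called lower (mean −0.60, adjusted p = 0.0102). It was called higher without knockdown replicate 1 (mean 0.97, adjusted p = 0.00819) and after quantile normalization (mean 0.35, adjusted p = 0.0433), so its direction as a list is not settled. The mean of the erythroid list was 0.94 with sex as a covariate.

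In the megakaryocyte and platelet list 8 of 9 measured members rose and 1 fell, adjusted over the list alone, with 2 rises over all genes. The latter were Pf4, the platelet factor 4 gene (20.1 against 3.19 FPKM, log2 change 2.43), and Itga2b, the integrin gene of the platelet fibrinogen receptor (9.66 against 2.20 FPKM, log2 change 1.62). Itgb3, its partner, had a log2 change of 1.50 and the thrombin receptor gene F2rl2 one of 1.18. Without knockdown replicate 1 or 4 or control replicate 1 or 4 the list-alone rises were 5. The list's mean log2 change was 1.09 (camera adjusted p = 0.000829, adjusted p = 0.797 with an estimated correlation). In the monocyte and macrophage list 3 of 20 members rose, adjusted over the list alone, and 0 over all genes. They were the Fc receptor gene Fcgr1 (log2 change 1.08) and the chemokine receptor genes Cx3cr1 (1.02) and Ccr2 (1.54). These 3 rises were 0 without knockdown replicate 2 or control replicate 4, 1 without knockdown replicate 4 or control replicate 2, and 13 without knockdown replicate 1. This list had a mean log2 change of 0.77 (camera adjusted p = 0.00233, adjusted p = 0.797 with an estimated correlation), of 0.40 without replicate 4 of both groups (adjusted p = 0.248), of 0.47 with the B cell covariate (adjusted p = 0.145) and of 0.41 with array weights (adjusted p = 0.294).

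The neutrophil and granule list moved in both directions. Of 14 measured members, 5 fell and 4 rose, adjusted over the list alone, and over all genes 3 fell and 0 rose. Besides Ngp, Camp and Ltf, the smallest p belonged to Mpo, the myeloperoxidase gene of primary granules, which rose over the list alone (19.1 ± 12.9 against 3.42 ± 2.02 FPKM, log2 change 2.05). The mean log2 change was −0.56 and the median −0.83 (camera adjusted p = 0.00592, adjusted p = 0.797 with an estimated correlation). Without knockdown replicate 2 the mean of the neutrophil and granule list was −0.31 and the adjusted p 0.0958. It was −0.23 without control replicate 1, −0.89 without control replicate 2 and −0.86 without knockdown replicate 4. With sex as a covariate, against control replicate 1 alone, the mean was −1.55. The call of the neutrophil and granule list was also lost at a mean of at least 5 FPKM, after quantile normalization and after median-of-ratios scaling (adjusted p = 0.116, 0.0729 and 0.0604). Of its members 4 rose whichever of 7 libraries was left out, and 1, Mpo, without control replicate 4.

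**Figure D4:**
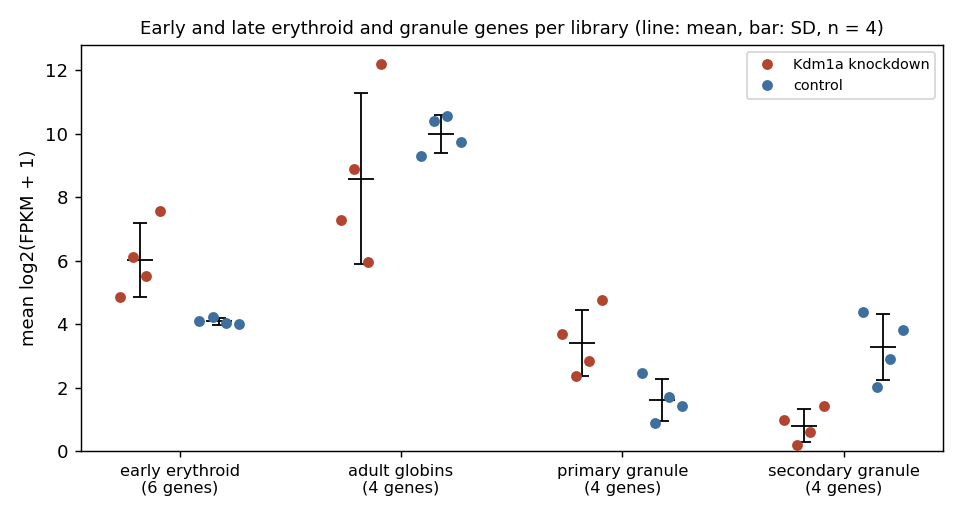
Mean log2(FPKM + 1) per library (vertical axis, from 0) of early erythroid genes, adult globin genes, primary granule genes and secondary granule genes. Each point is 1 library, the line is the mean and the bar the SD (n = 4). The sets were picked after their values were seen. Early erythroid genes averaged 6.03 against 4.09 and secondary granule genes 0.81 against 3.28.

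Interferon-stimulated genes were higher. In the type I interferon response list 31 of 32 measured members had a positive log2 change, 20 rose adjusted over the list alone, and 3 rose over all genes. The 3 were Oas2 (5.15 against 1.34 FPKM) and Oasl2 (27.5 against 4.04 FPKM), of the oligoadenylate synthetase family, and the receptor transporter gene Rtp4 (20.8 against 3.46 FPKM). Irf7, the interferon-inducible transcription factor gene, had 37.7 against 10.7 FPKM. The mean log2 change was 0.97 (camera adjusted p = 4.71e-09, adjusted p = 0.797 with an estimated correlation). Among sensors of double-stranded RNA, 4 of 13 rose adjusted over the list alone and 2 over all genes, Eif2ak2, which encodes the kinase PKR (log2 change 1.02), and Ifih1, which encodes the sensor MDA5 (log2 change 1.64). Dhx58 had a log2 change of 0.73. The 4 rises were 2 without knockdown replicate 2 or 4 or control replicate 1, 3 or 4. As a list these sensors did not pass (mean 0.28, camera adjusted p = 0.450). The interferon gamma list had a mean log2 change of 0.47 with 0 of 25 members past either threshold (camera adjusted p = 0.0283, adjusted p = 0.797 with an estimated correlation). Its call was lost without knockdown replicate 1 or 5 or control replicate 2 or 4 (adjusted p = 0.0511, 0.379, 0.0726 and 0.173). It was also lost with array weights (adjusted p = 0.0721) and at a mean of at least 5 FPKM (adjusted p = 0.152). With sex as a covariate its mean was 0.11.

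Cell cycle genes had positive log2 changes, but none passed over all genes. All 32 measured S phase members had a positive log2 change, and 17 rose adjusted over the list alone, 0 over all genes. The 17 were 0 without knockdown replicate 2 or control replicate 1, 3 or 4, 10 without knockdown replicate 4 and 31 without knockdown replicate 1. The S phase list had a mean log2(FPKM + 1) of 5.10 ± 0.63 against 4.22 ± 0.18 (SD, n = 4; exact permutation p = 0.0286; camera adjusted p = 5.46e-09, adjusted p = 0.797 with an estimated correlation). Cdca7 had 44.8 against 15.6 FPKM, the chromatin assembly factor gene Chaf1b 25.7 against 6.70 FPKM, and the exonuclease gene Exo1 15.2 against 7.70 FPKM. All 34 mitosis members also had a positive log2 change, with a mean of 0.84 and 0 members past either threshold (camera adjusted p = 5.26e-07, adjusted p = 0.797 with an estimated correlation). Without knockdown replicates 1, 5 and 4 in turn, 28, 23 and 2 mitosis members rose adjusted over the list alone, and 0 with any of the remaining libraries left out. Their examples were Anln, Ccnb1 and Tpx2 with log2 changes of 1.44, 1.47 and 1.03. Knockdown replicate 4 had the highest level of both lists, 5.97 and 6.14, against 4.05 to 5.12 and 4.12 to 5.14 in the other 7 libraries, and without it the mean of the mitosis list was 0.48. With the B cell covariate the means of the S phase and mitosis lists were 0.49 and 0.37, both still called (adjusted p = 8.03e-06 and 0.00542). Of the list of MYC targets and ribosome biogenesis, 29 of 30 members had a positive log2 change and 0 passed (mean 0.42, camera adjusted p = 0.00124, adjusted p = 0.797 with an estimated correlation). The B cell covariate ended this call (mean 0.24, adjusted p = 0.145). Nop56, Cdk4 and Ncl had log2 changes of 0.64, 0.74 and 0.64. Myc itself had 126 ± 15.2 against 113 ± 42.6 FPKM.

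Plasma cell and secretory genes lay lower on average. All 12 measured plasma cell members had a negative log2 change and 5 fell, adjusted over the list alone, with 0 over all genes. Derl3, a gene of protein degradation at the endoplasmic reticulum, had 18.5 against 58.2 FPKM, Mzb1, an antibody secretion factor gene, 347 against 644 FPKM, Prdm1, the plasma cell regulator BLIMP1, 5.29 against 16.9 FPKM, and Xbp1 67.1 against 112 FPKM. The mean log2 change was −0.84 (camera adjusted p = 1.56e-07, adjusted p = 0.797 with an estimated correlation). In the unfolded protein response list 17 of 20 members had a negative log2 change and 6 fell, adjusted over the list alone, with 0 over all genes. Of these the chaperone gene Hsp90b1 had 262 against 458 FPKM, Creld2 51.0 against 110 FPKM, and Herpud1 73.8 against 150 FPKM. Its mean was −0.43 (camera adjusted p = 1.56e-07, adjusted p = 0.555 with an estimated correlation). Xbp1 belongs to both lists. The 5 plasma cell falls were 0 without knockdown replicate 2 or 4 or control replicate 1, and 8 without control replicate 2. The 6 falls of the unfolded protein response list were 0 without knockdown replicate 2 or control replicate 1, 2 without control replicate 2 and 1 without control replicate 4.

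B cell genes lay lower on average, with 0 members past either threshold. Of 18 B cell markers 16 had a negative log2 change (mean −0.49, camera adjusted p = 6.13e-06, adjusted p = 0.797 with an estimated correlation). Pou2af1 had 127 ± 46.8 against 205 ± 50.9 FPKM, Fcrla 195 ± 80.3 against 302 ± 47.5 FPKM and Cd79a, a signalling chain of the B cell receptor, 716 ± 254 against 1094 ± 163 FPKM. The B cell receptor signalling list had a mean of −0.43 (camera adjusted p = 8.12e-07), with Plcg2 at 56.7 against 105 FPKM and Nfatc1 at 92.0 against 216 FPKM. The B-1 list had a mean of −0.29 (camera adjusted p = 0.0116), with Bhlhe41 at 27.1 against 52.4 FPKM and the myeloid integrin gene Itgam at 12.8 against 5.48 FPKM. Both had an adjusted p = 0.797 with an estimated correlation. Knockdown replicate 4 had the lowest B cell level, 6.01 against 7.24 to 7.58 in the other 7 libraries. Without it the means of these 3 lists were −0.14, −0.20 and −0.08, and without knockdown replicate 5 that of the B-1 cell list was −0.51. The class II antigen presentation list had a mean of −0.20 (camera adjusted p = 0.0159, adjusted p = 0.797 with an estimated correlation), and of 0.08 without knockdown replicate 4 (adjusted p = 0.461). Without control replicate 3 the mean of the antigen presentation class II list was −0.11 (adjusted p = 0.0844), −0.36 without control replicate 4 and −0.32 without knockdown replicate 1. The class II call was also lost with the B cell covariate (mean 0.17, adjusted p = 0.986), after quantile normalization (adjusted p = 0.181) and without a filter (adjusted p = 0.0569), and that of the B-1 cell list after quantile normalization (adjusted p = 0.0736).

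Oxidative phosphorylation genes (46 of 46 positive, mean log2 change 0.44, camera adjusted p = 0.000584) and mitochondrial ribosome genes (25 of 26 positive, mean 0.42, camera adjusted p = 0.00173) were higher as lists, with 0 members past either threshold. Both had an adjusted p = 0.797 with an estimated correlation. Without knockdown replicate 4 the adjusted p were 0.0908 and 0.0524, without control replicate 4 that of the former was 0.0621, and without both libraries the means were 0.07 and 0.17 (adjusted p = 0.762 and 0.281). The B cell covariate ended both calls (means 0.17 and 0.24, adjusted p = 0.587 and 0.217), as did array weights (adjusted p = 0.655 and 0.143). In glycolysis 4 of 20 members rose, adjusted over the list alone, and 2 over all genes. These 2 were the phosphofructokinase gene Pfkm (21.3 against 2.29 FPKM) and the lactate transporter gene Slc16a3 (3.01 against 1.07 FPKM). Hk1 and Slc2a3 had log2 changes of 1.29 and 1.11. As a list glycolysis did not pass (camera adjusted p = 0.0963), although it did without control replicate 2 or 3 (adjusted p = 0.0449 and 0.041), without a filter (0.00703) and after quantile normalization (0.0307). With sex as a covariate its mean was 0.41.

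Camera with a preset correlation of 0.01 called 16 of the 40 lists, 9 higher and 7 lower. With the correlation estimated per list it called 0, with 1 list at an unadjusted p under 0.05. The self-contained test fry called 0, with 12 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.0709. The other 24 lists did not pass. Among them were KDM1A complex and partners (mean 0.40, adjusted p = 0.450, 1 of 17 members past the threshold, Gfi1b), T cells (20 of 20 positive, mean 0.47, adjusted p = 0.199) and cytotoxic lymphocytes (13 of 13 positive, mean 0.59, adjusted p = 0.158). T cells passed without knockdown replicate 4 or control replicate 1, with the B cell covariate and with the replicate block (adjusted p = 0.0222, 0.0011, 0.00283 and 0.000542). With sex as a covariate, against control replicate 1 alone, the mean of the T cell list was −0.38. Its mean was 0.23 without control replicate 4 and 0.27 without knockdown replicate 1 (adjusted p = 0.752 and 0.846). Cytotoxic lymphocytes passed without control replicate 1 or 3, with the B cell covariate and with the replicate block (adjusted p = 0.00647, 0.00978, 0.0382 and 0.000374). The mean of the cytotoxic lymphocyte list was 0.25 without control replicate 4 (adjusted p = 0.731) and −0.20 with sex as a covariate. The T cell genes with the smallest p were Trbc1 and Trbc2, with log2 changes of 0.75 and 0.93. In 6 of the 24 the mean log2 change was positive and the test's direction downwards, since camera compares a list with all other genes.

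Levels of 14 cell type marker lists were also compared per library with a two-sided exact permutation test. None of the 14 passed after adjustment, which the 70 assignments allow only if more than 8 lists reach the smallest p. The stem and progenitor level was 3.88 ± 0.52 against 2.38 ± 0.22, and the megakaryocyte and platelet level 2.37 ± 0.47 against 1.28 ± 0.27 (SD, n = 4; exact p = 0.0286 and adjusted p = 0.20 each). Over all 12 stem and progenitor members, those under the filter included, the levels were 1.95 ± 0.40 against 0.95 ± 0.09 (SD, n = 4). The plasma cell level was 4.73 ± 0.39 against 5.57 ± 0.53 and the monocyte and macrophage level 4.83 ± 0.50 against 4.06 ± 0.38 (exact p = 0.0571 and adjusted p = 0.20 each). The B cell level was 7.04 ± 0.69 against 7.52 ± 0.08 (exact p = 0.0857, adjusted p = 0.24). The remaining 9 lists had an adjusted p of 0.267 to 0.771.

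The most abundant immunoglobulin heavy chain variable (Ighv) segment held between 37.5% and 89.2% of Ighv RNA per library. In knockdown replicates 1 and 2 this was Ighv11-2, with 40.9% and 37.5% of summed Ighv FPKM, in replicate 5 Ighv1-52 (66.8%) and in replicate 4 Ighv1-55 (61.6%). In the controls it was Ighv1-55 in replicates 1 and 3 (52.1% and 89.2%), Ighv2-5 in replicate 2 (59.4%) and Ighv5-16 in replicate 4 (82.3%). The top share averaged 51.7% ± 14.6 in knockdown and 70.8% ± 17.8 in control libraries (SD, n = 4; exact permutation p = 0.171). The share of the 2 most abundant segments differed by −23.8 points (exact permutation p = 0.0571). Summed Ighv RNA was lower, between 2092 and 6405 FPKM in knockdown and between 7182 and 14295 FPKM in control libraries (log2 difference −1.17, exact permutation p = 0.0286). Similar segments can share fragments, and no clone was called from these shares.

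Of the genes named whatever their values, Rcor1, the corepressor that binds KDM1A, had 18.6 ± 2.75 against 12.8 ± 3.47 FPKM (SD, n = 4; limma adjusted p = 0.232). Gfi1 had 4.45 ± 2.10 against 6.50 ± 3.40 FPKM and Kdm1b 6.19 ± 1.21 against 6.42 ± 1.25 FPKM. Cd5, a surface marker of chronic lymphocytic leukaemia B cells, had 25.4 ± 9.83 against 29.9 ± 12.4 FPKM. The survival gene Bcl2 had 16.6 ± 7.37 against 25.8 ± 5.09 FPKM, and Mki67, a proliferation marker, 91.2 ± 54.6 against 55.9 ± 17.9 FPKM. None of these 5 passed (adjusted p between 0.291 and 0.919). Mouse Tcl1 was listed at 0 in all 8 libraries, and the human transgene was not analysed here.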

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

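The values here were picked out because 1 library lay far from the other 3 of its group, by a rule fixed beforehand. Of 276 groups examined 13 were picked, and chance alone would pick about as many, 1 in 20. No technical or biological explanation was tested for these single values. Of the 13, 8 belonged to knockdown replicate 4 and 3 to control replicate 4.

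Knockdown replicate 4 lay below the other knockdown libraries in B cell genes and lists, on the log2(FPKM + 1) scale. Spib had 5.91 against 7.61 to 7.89, Tnfrsf13b 5.69 against 6.83 to 7.07, Plcg2 4.61 against 6.08 to 6.13 and Herpud1 5.53 against 6.33 to 6.45. The B cell list had 6.01 against 7.24 to 7.46, and the B cell receptor signalling list 5.40 against 6.27 to 6.36. The class II antigen presentation list had 6.45 against 7.49 to 7.63, and the NF-kB target list 4.06 against 4.64 to 4.71.

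Control replicate 4 lay above the other controls in Gfi1b (3.64 against 2.46 to 2.54) and Pou2af1 (8.14 against 7.46 to 7.52). It lay below them in the immediate early gene list (4.15 against 4.44 to 4.50). Control replicate 2 had 3.29 in Tnfsf18 against 2.58 to 2.62. Knockdown replicate 2 had 3.17 in Oas2 against 2.30 to 2.42.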

How the results depend on the processing

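Sex and erythroid covariates, both replicate 4 libraries left out and failed estimates left out were chosen after seeing the data. The planned sex covariate needed both sexes in each group and was not run. The count of 224 changed genes was 24 with pseudocount 5, 2 without a filter and 71 at a mean of at least 5 FPKM. It was 126 after quantile normalization, 131 after median-of-ratios scaling, 514 at an adjusted p of 0.10 and 761 with array weights. With the B cell covariate it was 78 and with the erythroid covariate 601. It was 120 without both replicate 4 libraries and 8 to 333 with 1 library left out. In every setting all of the 224 that were tested kept their sign. In most settings, those with libraries left out among them, this had to be so, since their groups did not overlap. Only the scalings and the B cell and erythroid covariates could have changed a sign. Without a filter 28861 genes were tested, and the causes of the other shifts were not tested. Same-numbered libraries had deviations correlated at 0.163, 0.047 and −0.118. These were not set against other pairs, so a shared pairing is neither shown nor excluded. With the replicate block over numbers 1, 2 and 4 limma called 0 genes, with 2088 at an unadjusted p under 0.05, and the Kdm1a difference was −0.41. Camera with this block did not call the interferon gamma response list (mean 0.37, adjusted p = 0.166). It called higher the T cell, cytotoxic lymphocyte, dendritic cell and chemokine lists (adjusted p = 0.000542, 0.000374, 0.0265 and 0.031), which were otherwise uncalled. It also called lower the histone demethylase and methyltransferase list (adjusted p = 0.0142).

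The 16 called lists were 12 to 20 in the other settings but 0 with an estimated correlation and 0 with fry. The Kdm1a difference stayed negative and short of the adjusted threshold, between −0.26 and −0.61. The Ighv share difference of −19.1 points ranged from −12.9 to −25.3. The first component carried 38.5% at a mean of at least 5 FPKM and 46.9% without immunoglobulin segments.

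Uncalled lists that stayed uncalled aside, 4 lists reversed their direction against other genes. With the B cell covariate these were the antigen presentation class II list (mean 0.17) and the erythroid list (mean −0.60, then called lower). The others were the oxidative phosphorylation list without both replicate 4 libraries (mean 0.071) and the T cell list with the sex covariate (mean −0.38, against control replicate 1 alone). Uncalled genes that changed sign were Kdm1b (0.031 with the replicate block, 0.12 with the B cell and 0.016 with the erythroid covariate, −0.17 to 0.076 with 1 library left out), Cd5 (0.16 with the B cell covariate, −0.48 to 0.043 with 1 left out), Myb (−0.11 to 0.64 with 1 left out), and with the sex covariate Trbc1 (−0.13), Trbc2 (−0.23), Cd6 (−0.09) and Cd247 (−0.27). These causes were not tested. Of single-gene values, 1707 kept their side, 302 lost and 59 gained a call. Of the values of 22 lists, those called or described, 453 kept their side, 32 lost and 16 gained a call. Other uncalled lists, such as antigen presentation class I and cholesterol synthesis, also gained calls in some settings and are not in this count. At this depth 1 fragment on 1 kilobase is worth up to 0.0269 FPKM, which limits the 127 rises with controls under 2 FPKM.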

Other observations

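All tests here were chosen after the result was seen, except the counts over other splits of the libraries. Symbol families were genes that share the letters before the first digit of the symbol. Among 755 such families with at least 3 expressed members, 3 were over-represented among the 210 higher genes (hypergeometric test). Aquaporin genes, which encode water and glycerol channels, rose in 3 of 3 expressed members, Aqp1, Aqp9 and Aqp11 (adjusted p = 0.00322). Of genes named Gna and a number, which are only a part of the G protein alpha subunit genes, 3 of 5 rose, Gna12, Gna14 and Gna15 (adjusted p = 0.0157). Of galectin and related genes 3 of 7 rose, Lgals7, Lgals9 and Lgals3bp (adjusted p = 0.0358). The rises kept their sign under every scaling. Of fatty acid desaturases 2 of 3 rose, Fads1 and Fads2 (adjusted p = 0.118). These genes fall outside the naming rule and were picked after their values were seen.

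Lineage genes were also grouped by stage of maturation, into sets picked after their values were seen, so no p-value is given for them. Means of 6 early erythroid genes (Gata1, Klf1, Epor, Car1, Ermap and Tfrc) were 6.03 ± 1.16 against 4.09 ± 0.10 on the log2 scale (SD, n = 4), while the 4 adult globin genes averaged 8.58 ± 2.69 against 9.99 ± 0.59. Among granulocyte genes the 4 primary granule genes Mpo, Elane, Prtn3 and Ctsg averaged 3.41 ± 1.05 against 1.63 ± 0.66, and the 4 secondary granule genes Camp, Ngp, Ltf and Lcn2, of which the first 3 are called falls, 0.81 ± 0.52 against 3.28 ± 1.03.

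Length trends differed between libraries. Across 10995 protein-coding genes, which are not independent replicates, the deviation of control replicate 4 from the other controls had a Spearman correlation of 0.23 with exon length, and the median deviation was −0.38 in the shortest of 4 equal bins of genes. Control replicate 3 had a correlation of −0.31. Knockdown replicate 4 had one of −0.21 and a median deviation of 0.19 in the shortest bin, opposite to control replicate 4, so that short genes lay higher in the first and lower in the second. What this adds to the list calls was not measured.

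The first pattern weighed is the 224 changed genes, 210 of them higher. Only 1 of the 35 splits of the 8 libraries, the real one, gave as many, and the highest other split gave 8. This is the smallest share that 35 splits can give, so chance is not excluded for the count. The other splits mix the groups, so a real difference would itself lower their counts. RNA from maturing erythroid cells is argued against in knockdown replicates 1, 2 and 5, where the 4 adult globin transcripts lay below every control (difference −2.62 on the log2 scale). Over 8 late erythroid transcripts, which include these globins, knockdown replicates 1 and 5 (5.18 and 4.86) also lay below the lowest control, at 6.88. Knockdown replicate 2, at 6.96, did not, so the argument is weaker there. In knockdown replicate 4 these transcripts were higher by 2.44, and this source stays open there, though the count was 203 without that library, with 172 genes shared. The 6 early erythroid genes had 4.86, 6.13 and 5.53 in knockdown replicates 1, 2 and 5 against 4 to 4.23 in the controls. The globin values therefore do not speak against earlier erythroid cells in these libraries. RNA from erythroid and other myeloid precursors also stays open, since the stem and progenitor list, fixed before the data were examined, was higher by 1.50 over the 4 members that reached the expression filter (1.95 against 0.95 over all 12), and more such cells cannot be told apart from higher transcription within cells in bulk RNA. Sex cannot be told apart from the knockdown with 1 female control. Its correction left a median log2 change of 1.66 over the 210 genes against 1.81 before. That median had to stay positive, since the groups of these genes do not overlap and control replicate 1 lies below every knockdown library. Over all genes tested the median log2 difference was 0.07 with the correction and 0.13 without it. The values therefore do not speak against sex.

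The second pattern is the fall of secondary granule genes. A lower share of all granulocyte-lineage cells is argued against, because 4 of the 14 measured members of the neutrophil and granule list, the primary granule genes above, rose when adjusted over the list alone, while 5 fell. Without control replicate 4 it was 1 that rose and 3 that fell. Fewer maturing neutrophils beside more early granulocyte precursors may account for it, since 6 other late neutrophil genes (Cxcr2, Ly6g, Retnlg, Mmp9, S100a8 and S100a9) had a log2 difference of −1.04, but those groups overlapped and altered expression within the cells cannot be told apart. Preparations of mononuclear cells usually remove most mature granulocytes, and the labels do not describe the isolation, so a carry-over that differed between libraries stays open as well. The female control had the highest secondary granule mean, 4.39 against 0.21 to 1.42 in the knockdown libraries. With sex as a covariate the difference over these 4 genes was −3.58 in place of −2.48, which restates that 1 library. Camp, Ngp and Ltf were named for groups without overlap, so in them it had to lie above every knockdown library. With 1 female control these values cannot decide on sex, which is not excluded. The knockdown itself also stays open.

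The third pattern is the higher S phase and mitosis lists. The count of called lists does not exclude chance, since 20 of the 35 splits called at least the 16 lists of the real one, and the highest other split called 24, which points to correlated genes within lists. A low level in control replicate 4 alone is argued against by the size of the differences. Without that library the S phase and mitosis differences were 0.83 and 0.85 on the log2 scale in place of 0.89 and 0.84. Both lists were still called, but calls at the preset correlation are frequent in other splits and add little. The S phase members that rose over the list alone went from 17 to 0. Cycling erythroid cells in proportion to the level of the whole erythroid list are argued against as the whole cause. With that level as a covariate the median over S phase members was 0.75 ± 0.19 (median SE) in place of 0.89 ± 0.31. The median over mitosis members was 0.65 ± 0.17 in place of 0.86 ± 0.36. Then 10 and 9 members passed over all genes where 0 had, but through the smaller SE, since the medians shrank. A smaller SE means that the erythroid level followed part of the spread of these genes between libraries, so these passes do not argue against erythroid cells. As part of the cause cycling erythroid cells stay open, since the S phase mean was 0.71 in place of 0.89. The erythroid list mixes early genes that were higher with globin genes that were lower on average. Its level need not follow early, cycling erythroid cells. Over the 6 early erythroid genes, picked after their values were seen, knockdown replicates 1, 2, 5 and 4 had 4.86, 6.13, 5.53 and 7.58. Their S phase levels, 4.5, 5.12, 4.83 and 5.97, ranked alike, so early erythroid cells stay open as the whole cause. The cell type that carries the S phase and mitosis transcripts was not measured.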
